A study of Mus musculus with 12 samples.

How the data were processed

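RNA was measured on 12 two-colour Agilent arrays, 4 for each of 3 groups of mature adipocytes of the mouse line 3T3-L1, a preadipocyte line that stores lipid once differentiated. The cells had received small interfering RNA by Amaxa electroporation, as a control (control-si), against Usp7 (USP7-si) or against TIP60 (TIP60-si). Kat5 is the gene symbol of TIP60. The labels give no sequences and do not say whether all arrays of a group received the same ones. Each array carried the adipocyte sample in 1 dye and a common reference, RNA of undifferentiated 3T3-L1 cells, in the other. Within each group the sample was in Cy3 on replicates 1 and 3 and in Cy5 on replicates 2 and 4, so each group held 2 arrays of either orientation. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples.

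Per the protocol text, the authors scanned the arrays on an Agilent G2565BA scanner, extracted the features with Imagene and applied print-tip loess to the gene probes without background correction. The deposited scanner files give the intensity of each spot and of its local background in both dyes, on a linear scale. The deposited normalized files give the intensity of both dyes after the authors' normalization. The deposited value table gives log2 ratios, which equal log2 of the sample over the reference in the normalized files to within 5e-06, so its scale and direction were settled from the values. The column medians of that table ran from -0.00915 to 0.00526, so the authors' ratios are centred near 0. Software versions of the scanner and of Imagene are not stated.

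The array held 45220 spots, of which 41174 were gene probes and 4046 were control spots. Of the gene probes, 34186 had 1 gene symbol, 6988 had none and 0 had several. The symbols covered 18295 genes, 8946 of them with more than 1 probe. Symbols were brought up to date with the synonyms of a mouse RefSeq gene table: 30365 probes had a current symbol, 3726 were updated and 95 matched neither. Median raw signal in the sample dye ran from 124 to 196 per array, against median backgrounds of 39.5 to 46. Between 85.2% and 98.3% of the gene probes stood more than 2 background SDs above background. The number of arrays limits the precision.

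The scanner intensities were background corrected with normexp (offset 50) and normalized within each array by loess, with the control spots given weight 0, in limma 3.58.1 under R 4.3.3. All ratios were turned to log2 of sample over reference. No scaling between arrays was applied. One linear model over all 12 arrays, with group and dye orientation as terms, was fitted with lmFit and eBayes, and 3 comparisons were drawn from it: USP7-si versus control-si, TIP60-si versus control-si and TIP60-si versus USP7-si. Tests were two-sided, with Benjamini-Hochberg adjustment over the 41174 probes and a threshold of adjusted p below 0.05. Errors of fold changes are standard errors (SE) of the model, and errors of group means are standard deviations (SD) over 4 arrays. Group means and SDs are of log2 ratios corrected for the fitted dye term.

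In all, 34 gene lists were fixed, with 702 of their 747 members measured, and the cytosolic ribosomal list was the least complete (17 of 27). Each gene was represented by its brightest probe. Lists were tested with camera (limma, preset correlation of 0.01) with adjustment over the 34 lists, and again with an estimated correlation and with fry, whose directional test asks whether a list's genes move 1 way on balance. Member counts are given over all probes and also adjusted over the list alone. Genes were named by a rule: Usp7 and Kat5; the 10 largest rises and the 10 largest falls of each knockdown against control-si, and the 5 largest either way between the knockdowns, among called probes whose 4 arrays of 1 group all lay beyond the 4 of the other and whose symbol is not a clone or predicted-gene name, with 1 probe per gene; the 5 largest either way among genes called in both knockdowns; and up to 4 members of each list with the smallest p. Any gene named outside the rule is said to have been chosen after its values were seen.

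Probes called in both knockdowns were counted with the number expected of independent lists, and with the controls split into 2 dye-balanced parts so that no control array served both knockdowns. The covariance of the fold changes was set against 100 simulations of unchanged groups with the same controls. The response to each knockdown was also compared, across probes, with the difference between control-si adipocytes and the reference, using different control arrays on the 2 sides. Both are descriptions across genes, which are not independent replicates.

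The tests were run on simulated data with 41174 genes, 200 of them changed. For USP7-si versus control-si, 67 of 67 simulated changes of 1.5-fold, 67 of 67 of 2-fold and 66 of 66 of 4-fold were called, with 6 false calls among 206. For TIP60-si versus control-si, 66 of 67 changes of 1.5-fold, 67 of 67 of 2-fold and 66 of 66 of 4-fold were called, with 7 false calls among 206. Changes below 1.5-fold were not simulated. In the real data the median size of a called log2 fold change was 0.398 in USP7-si and 0.291 in TIP60-si, so the share of such changes found is not known. A simulated list of 30 genes shifted by -0.2 gave a camera adjusted p of 7.41e-40, and 0 of 33 unchanged lists were called by camera. The simulated genes were independent of each other, which real genes are not. Over the other splits of the real arrays, a median of 6 lists was called for USP7-si versus control-si and of 4 for TIP60-si versus control-si. Some of these splits hold part of a real difference, so these medians are not counts without an effect.

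The groups, comparisons, tests, gene lists, naming rule and most alternatives were set before the data were examined. The alternatives changed the background correction, the normalization, the source of the values, the filter on dim probes, the dye and replicate terms, the arrays in the fit, the variance model, the test, the fold minimum, the set test, the probe chosen for a gene and the control arrays, and left out each array in turn. Scaling all arrays to an equal spread of log ratios was added after seeing the data for every result, and median centring was added for the gene lists. Replicate numbers showed no clear pairing of the arrays. After dye correction, 3 of the 12 correlations between arrays of the same number exceeded 0.1, within a range of -0.291 to 0.307. The fit itself lowers these correlations, so they do not exclude a shared effect, and replicate is a term only in an alternative. Probe sequences, off-target matches of the small interfering RNAs and the authors' quantitative PCR of the targets were not analysed here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.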

Results

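The data are log2 ratios of mature 3T3-L1 adipocytes over a common reference of undifferentiated 3T3-L1 cells, on 12 arrays: 4 of control-si, 4 of USP7-si and 4 of TIP60-si. USP7 is a deubiquitinase and TIP60 (gene Kat5) is a histone acetyltransferase, and the series title places them in 1 pathway of early fat cell formation. The comparisons ask which transcripts differ when either gene is silenced in differentiated cells, whether the knockdowns share a response, and whether that response runs along the difference between adipocytes and undifferentiated cells. Fold changes are log2 with their SE and rest on 4 arrays per group. Unless another test is named, p-values are from limma and adjusted over 41174 probes.

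The control-si cells carried the transcripts of mature fat cells. Adiponectin (Adipoq) stood 5.79 ± 0.24 (SD, n = 4) above the reference on the log2 scale, adipsin (Cfd) 5.34 ± 0.17, resistin (Retn) 4.88 ± 0.19 and the fatty acid binding protein gene Fabp4 4.83 ± 0.41. The lipid droplet coat gene Plin1 stood 2.72 ± 0.23 above it, the master regulator of adipogenesis Pparg 2.53 ± 0.14, and Cebpa, its partner in adipocyte transcription, 1.99 ± 0.12. The preadipocyte gene Dlk1 was at -1.42 ± 0.076 and the collagen gene Col1a1 at -1.45 ± 0.18, but the collagen gene Col3a1 at -0.35 ± 0.16 and the leptin gene Lep at 0.25 ± 0.087. The preadipocyte list had a median of -0.094, with 5 of 21 members below -1 and 2 above 1. The adipocyte identity list had a median of 2.53 over the reference, with 25 of 33 members above 1. The mitosis list also stood above the reference, at a median of 1.23 with 24 of 32 members above 1, among them the proliferation marker Mki67 at 1.87 ± 0.14. These marker genes were chosen after their values were seen, and the reference is 1 RNA, so no spread of undifferentiated cells is available.

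Each small interfering RNA lowered its own target. Usp7 fell in USP7-si with a log2 fold change of -1.64 (SE 0.10, adjusted p = 1.16e-05), to 32% of control-si, from a ratio over the reference of -0.11 ± 0.12 (SD, n = 4) to -1.76 ± 0.25. Kat5 fell in TIP60-si with a log2 fold change of -0.999 (SE 0.068, adjusted p = 1.17e-05), to 50% of control-si. All 4 arrays of the targeted group lay below all 4 of control-si in both cases. Usp7 in TIP60-si had a log2 fold change of -0.085 (adjusted p = 0.759) and Kat5 in USP7-si of -0.042 (adjusted p = 0.979), so neither change in the other target passed the test. Between the knockdowns, Usp7 was higher by 1.56 and Kat5 lower, at -0.96 (adjusted p = 1.05e-05), in TIP60-si. The values are of probe MMAB016154 for Usp7 and MMAB035272 for Kat5; a dimmer Usp7 probe, MMAB029582, had a log2 fold change of 0.028 in USP7-si (adjusted p = 0.986). Scaling all arrays to an equal spread, an alternative added after seeing the data, left Usp7 at -2.15 in USP7-si but without a call (adjusted p = 0.112).

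**Figure D1:**
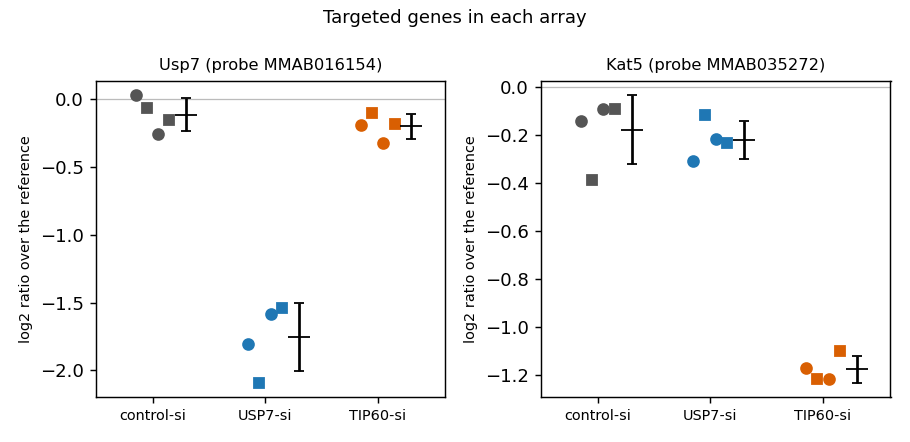
Log2 ratio over the reference of Usp7 and Kat5 in each array, corrected for the fitted dye term; circles are arrays with the sample in Cy3, squares with it in Cy5, and the black mark is the mean with its SD (n = 4). Usp7 is lowest in USP7-si (mean -1.76) and Kat5 in TIP60-si (mean -1.18).

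USP7-si versus control-si asks which transcripts depend on Usp7 in adipocytes. The immediate early transcription factor genes Egr1 and Fos rose most among named genes, by 0.89 (SE 0.11, adjusted p = 0.00415, 1.85-fold) and 0.88 (SE 0.082, adjusted p = 0.000421, 1.84-fold). Also higher were Pdcd4, which encodes an inhibitor of translation (0.54), the actin-binding gene Ablim1 (0.49), the Golgi protein gene Trip11 (0.47), the olfactory receptor gene Olfr598 (0.43), the matricellular growth factor-induced gene Ccn1 (0.43), the growth factor gene Pdgfa (0.40), the efflux transporter gene Abcc5 (0.36) and the homeobox gene Hoxa7 (0.36). After Usp7 itself, Filip1l fell most among named genes (-0.70, SE 0.10, adjusted p = 0.023). Next were the histone H2A genes H2ac13 (-0.58, SE 0.057, adjusted p = 0.000595) and H2ac23 (-0.54) and the chaperone gene Bag6 (-0.52). Lars2, a mitochondrial transfer RNA synthetase gene (-0.42), the replicative helicase gene Mcm6 (-0.41), the histone chaperone gene Set (-0.39), Lrrc58 (-0.39) and the thymidine kinase gene Tk1 (-0.38) fell as well.

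In all, 35 probes passed the threshold in USP7-si, 13 higher (4 by more than 1.5-fold) and 22 lower (3 by more than 1.5-fold), for 30 named genes and 5 probes without a symbol, and 2580 had an unadjusted p below 0.05. Of these 20 largest changes, 10 rested on 1 of several probes of the gene. The other 6 probes of Ablim1 ranged from -0.15 to 0.18 and the other 3 of Bag6 from -0.036 to 0.004. The other probes of Filip1l ranged from 0.011 to 0.029. Of the 20, Fos was called under all 25 alternatives, Usp7 and Bag6 under 24, H2ac13 and H2ac23 under 23 and Egr1, Ablim1 and Olfr598 under 21. Pdcd4 and Pdgfa were called under 16, Filip1l and Tk1 under 14, Ccn1 and Lrrc58 under 11, Lars2 and Set under 10, Mcm6 and Hoxa7 under 9 and Trip11 and Abcc5 under 7. After scaling to equal spread, of the 20 only Fos and Bag6 were called. There Ccn1 turned to -0.14 and Lars2 to 0.044, and Filip1l was at -0.040, Pdgfa at 0.036, Tk1 at -0.072 and Hoxa7 at 0.17. The Filip1l call was also lost without control-si replicates 2, 3 or 4 (adjusted p = 0.104, 0.0729, 0.132) or USP7-si replicates 1, 2 or 3 (0.117, 0.0682, 0.0848), within 0.00675 to 1 over all alternatives. The count was 3 with median centring in place of loess, 4 after scaling, 12 with plain background subtraction and 77 with array quality weights. Leaving out 1 array took it up to 49 (TIP60-si replicate 4), and down to 14 (control-si replicate 4 or USP7-si replicate 1), 16 (control-si replicate 2), 18 (USP7-si replicate 4) or 21 (USP7-si replicate 3).

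Cell division genes stood lower in USP7-si. The mitosis list ranked below the other genes (camera adjusted p = 6.6e-38), with a median log2 fold change of -0.33 and all 32 measured members below 0. For this list, adjusted p = 0.0638 with an estimated correlation, and fry gave 0.0202. Limma called 0 of the 32 over all probes, 29 had an unadjusted p below 0.05, and 29 fell adjusted over the list alone. Among its members were the kinesin gene Kif20a (-0.24, SE 0.042), the anaphase activator gene Cdc20 (-0.35, SE 0.069), the proliferation marker Mki67 (-0.40, SE 0.083) and the mitotic transcription factor gene Foxm1 (-0.21, SE 0.043). The list of the G1/S transition and DNA replication ranked lower too (camera adjusted p = 2.12e-24, median -0.21), and this call held: adjusted p = 0.0316 with an estimated correlation. Of its 39 members, Tk1 and Mcm6 fell over all probes and 26 fell adjusted over the list alone, among them the helicase gene Mcm2 (-0.35, SE 0.064) and the cyclin gene Ccnd2 (-0.30, SE 0.059). The list of ribosome biogenesis and MYC target genes (median -0.077, camera adjusted p = 0.000661, adjusted p = 0.0331 with an estimated correlation) and the proteasome list (median -0.046, camera adjusted p = 0.000729, adjusted p = 0.0331 with an estimated correlation) ranked lower by small amounts. Limma called 0 members of either over all probes or adjusted over the list alone, with 2 of 21 and 1 of 27 at an unadjusted p below 0.05. After scaling to equal spread the mitosis median was -0.057 and the G1/S median -0.091, both still called (adjusted p over all alternatives 6.26e-69 to 0.0638 and 8.48e-28 to 0.0316). The proteasome call was lost with median centring and after scaling, where its median was 0.0025 (0.000338 to 0.577), and the ribosome biogenesis call with median centring (0.000156 to 0.0826).

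In USP7-si the interferon list ranked lower (median -0.16, camera adjusted p = 3.8e-11), with 27 of 30 members below 0. For this list, adjusted p = 0.305 with an estimated correlation, and fry gave 0.262. Limma called 0 of the 30 over all probes, 13 had an unadjusted p below 0.05, and 3 fell adjusted over the list alone: Usp18, a protease that removes ISG15 (-0.42, SE 0.082), Xaf1 (-0.24, SE 0.064) and the ubiquitin-like modifier gene Isg15 (-0.40, SE 0.12). The cholesterol synthesis list ranked higher (median 0.092, camera adjusted p = 0.000333), with 20 of 20 members above 0. Here adjusted p = 0.339 with an estimated correlation, and after scaling to equal spread the median was -0.10 and the call was lost. Limma called 0 of its members over all probes or adjusted over the list alone, with 1 at an unadjusted p below 0.05, the sterol reductase gene Dhcr7 (0.17, SE 0.057). The list of USP7 binding partners and substrates ranked lower (median -0.067, camera adjusted p = 0.000729) with Usp7 itself among its members. For this list adjusted p = 0.0638 with an estimated correlation, and the call was also lost after scaling (median -0.0082). Usp7 was its only member called over all probes, and adjusted over the list alone 2 fell, Usp7 and the maintenance methylation gene Uhrf1 (-0.31, SE 0.082).

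No stable shift of adipocyte genes was found in USP7-si. The adipocyte identity list had a median of -0.092 (camera adjusted p = 0.0043), with 24 of 33 members below 0; adjusted p = 0.654 with an estimated correlation. Limma called 0 of its 33 members over all probes or adjusted over the list alone, and 4 had an unadjusted p below 0.05: the lipid droplet gene Plin4 (0.21, SE 0.072), the triglyceride synthesis genes Lpin1 (-0.15, SE 0.056) and Agpat2 (-0.20, SE 0.078) and the gluconeogenic gene Pck1 (-0.48, SE 0.19). USP7-si replicate 4 stood apart from the other arrays on this list, with a median ratio over the reference of 1.70 where the other 11 arrays lay between 2.255 and 2.741, and it had the narrowest spread of all log ratios (median absolute ratio 0.055, others 0.109 to 0.148). It also had the lowest median of the mitosis list (0.73), of the G1/S list (0.20) and, within USP7-si, of the interferon list (0.11). Without it the adipocyte identity median was 0.0087, without control-si replicate 2 it was -0.014, and both calls were lost. With no background correction and with the authors' values the call was lost too, and after scaling to equal spread the median was 0.49 and called upward (adjusted p over all alternatives 3.02e-09 to 0.78). The mitosis median without USP7-si replicate 4 was -0.27 and still called.

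The other called lists in USP7-si were small and lost their call with an estimated correlation. DNA damage response and repair had a median of -0.083 (camera adjusted p = 0.000729, adjusted p = 0.328 with an estimated correlation). Limma called 0 of its 24 members over all probes, with 8 at an unadjusted p below 0.05 in either direction and 1, the repair gene Brca1 (-0.24, SE 0.052), lower adjusted over the list alone. The citrate cycle list (median -0.049, camera adjusted p = 0.0161, adjusted p = 0.369 with an estimated correlation), the ATF4 and unfolded protein response list (-0.027, 0.0249, adjusted p = 0.205 with an estimated correlation), the oxidative phosphorylation list (-0.033, 0.0249, adjusted p = 0.644 with an estimated correlation) and the cytosolic ribosomal list (-0.046, 0.0476, adjusted p = 0.339 with an estimated correlation) had 0 members called by limma over all probes or adjusted over the list alone, and 3, 4, 0 and 1 at an unadjusted p below 0.05. After scaling to equal spread the citrate cycle median was 0.18 and the oxidative phosphorylation median 0.23. Leaving out 1 array ended these calls in several cases. The citrate cycle call ended without control-si replicates 1 (0.113) or 2 (0.189) or USP7-si replicates 3 (0.0825) or 4 (0.0692), within 0.0013 to 0.369 over all alternatives. The oxidative phosphorylation call ended without control-si replicates 1 (0.221) or 2 (0.58) or USP7-si replicates 3 (0.0825) or 4 (0.353), within 9.15e-07 to 0.644. The ATF4 call ended without control-si replicate 3 (0.0505) or USP7-si replicate 3 (0.0825), within 0.000484 to 0.349. The cytosolic ribosomal call ended without control-si replicate 3 (0.567), TIP60-si replicates 2 (0.0517) or 4 (0.0562) or USP7-si replicates 1 (0.155), 3 (0.0825) or 4 (0.178), within 0.000834 to 0.567.

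Other splits of these 8 arrays, some of which hold part of a real difference, gave a median of 6 called lists and at most 11, against the 13 called here. The remaining 21 lists were not called by camera in USP7-si. Within them 4 members rose over all probes: Fos and Egr1 of the immediate early list, Ccn1 of the extracellular matrix list and the endothelial receptor gene Tek (0.35, SE 0.047, adjusted p = 0.0104). Of these 21 lists, fry called the endothelial list and the heat shock and immediate early list upward (adjusted p = 0.0183 for both). The p53 target list had a median of 0.044 (camera adjusted p = 0.0914) and the endothelial list of 0.027 (0.098). The heat shock and immediate early list had a median of -0.017 but a mean of 0.10 and a test direction upward (0.142); adjusted over the list alone 4 of its members rose, Fos, Egr1, Ier2 (0.30) and Egr2 (0.27). Of the osteoblast list the secreted bone protein gene Spp1 (-0.52, SE 0.13) fell adjusted over the list alone; in the other 17 lists limma called 0 members over all probes or adjusted over the list alone, with 0 to 6 per list at an unadjusted p below 0.05. Camera adjusted p was 0.158 for lipolysis (median -0.041), 0.279 for fatty acid oxidation (-0.013), 0.294 for histone acetyltransferases and deacetylases (0.037), 0.302 for fatty acid and triglyceride synthesis (-0.018), 0.329 for Wnt signalling (0.019) and 0.363 for adipokines (-0.027). It was 0.433 for macrophage markers (median -0.0053, mean 0.037), 0.453 for insulin signalling (-0.013), 0.499 for apoptosis (0.042), 0.503 for osteoblast markers (-0.0019), 0.541 for TIP60 complex subunits (-0.0023) and 0.606 for brown adipocyte markers (0.0032), the circadian clock (0.015) and lysosome and autophagy genes (0.021). It was 0.679 for the extracellular matrix (0.013), 0.787 for NF-kB genes (median 0.011, mean -0.022), and 0.845 for muscle markers (median 0.015, mean -0.00075) and preadipocyte markers (0.0065).

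**Figure D2:**
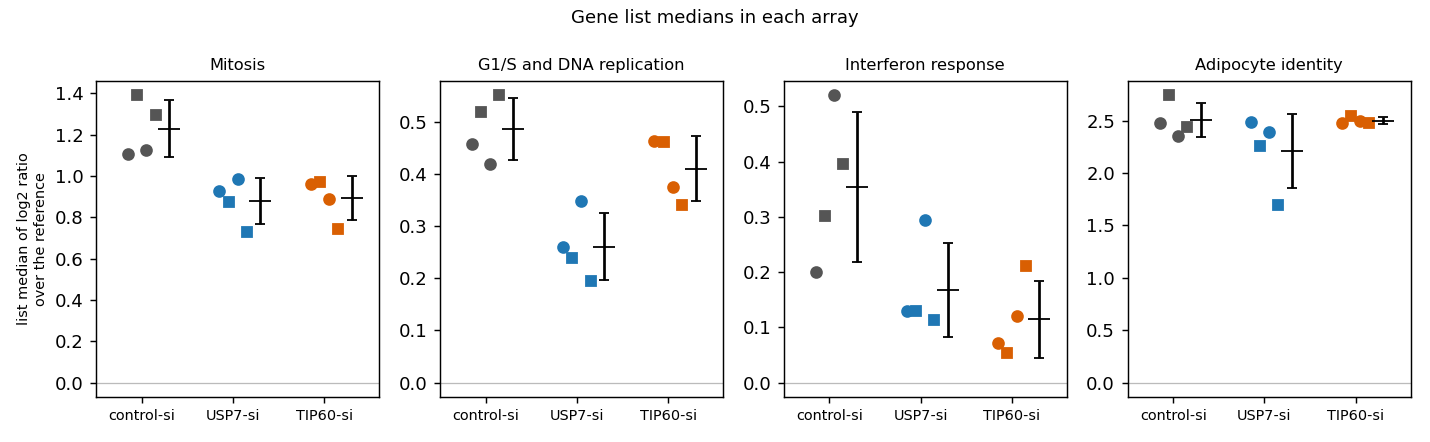
Median log2 ratio over the reference of the mitosis, G1/S, interferon and adipocyte identity lists in each array; circles are arrays with the sample in Cy3, squares with it in Cy5, and the black mark is the mean with its SD (n = 4). Every USP7-si and TIP60-si array has a lower mitosis median (at most 0.99) than every control-si array (at least 1.11), and USP7-si replicate 4 has the lowest adipocyte identity median (1.70).

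TIP60-si versus control-si asks which transcripts depend on Kat5 in adipocytes. Among the largest rises of named genes were those of Prl2c3 (0.999, SE 0.15, adjusted p = 0.00289), Prl2c1 (0.82) and Prl2c5 (0.82). These are members of the placental prolactin family. Ear10 (0.90, SE 0.14, adjusted p = 0.00388) and Ear-ps9 (0.81) of the eosinophil-associated ribonuclease family rose too. Also higher were the late endosome GTPase gene Rab7 (0.85, 1 of 3 probes, the others at 0.0028 and 0.1), Olr1, a receptor for oxidized lipoprotein (0.85), the cytokine gene Il33 (0.79, SE 0.095, adjusted p = 0.000822), Asb12 (0.72) and the olfactory receptor gene Olfr1099 (0.72). Papss1, which makes the sulfate donor of the cell, fell by 1.38 (SE 0.088, adjusted p = 1.17e-05, 2.6-fold), and Cyp51, a demethylase of cholesterol synthesis, fell by 1.17 (SE 0.10, adjusted p = 7.41e-05). Cavin3, a coat gene of caveolae (-1.03, SE 0.073), Kat5, the matrix proteoglycan gene Ogn (-0.94), Bri3bp (-0.93), Ahcyl1, which binds the inositol trisphosphate receptor (-0.90), Apol9a (-0.86), the tetraspanin gene Cd151 (-0.86) and Lrrc75b (-0.84) fell as well.

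In all, 1556 probes passed the threshold in TIP60-si, 515 higher and 1041 lower, for 1219 named genes, and 7090 had an unadjusted p below 0.05; 32 rose and 47 fell by more than 1.5-fold. The other 3 probes of Cyp51 ranged from -0.22 to -0.038, and whether each Prl2c and Ear probe reads its own gene was not tested here. In TIP60-si the medians of 5 Prl2c and 5 Ear probes (0.82 and 0.77) were 0.18 and 0.49 after scaling to equal spread, where the Prl2c genes lost their calls. Papss1, Cavin3, Kat5, Bri3bp and Lrrc75b were called under all 25 alternatives, and Rab7 under 15 of them. Of the other 14 largest changes, Asb12 and Olfr1099 were called under 21, Olr1 and Prl2c5 under 22, Ear10, Prl2c1 and Prl2c3 under 23 and the rest under 24. After scaling to equal spread 7 of the 20 were called, and Ogn was at -0.28 (adjusted p = 0.973, within 0.000587 to 0.973 over all alternatives). The count was 26 with median centring (4 higher, 22 lower), 97 after scaling to equal spread and at most 1843, with no background correction, and leaving out 1 array took it to 736 (control-si replicate 2), 743 (control-si replicate 4), 859 (control-si replicate 1) or 884 (TIP60-si replicate 3).

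Cell division and interferon genes stood lower in TIP60-si. The mitosis list ranked lower (median -0.31, camera adjusted p = 3.54e-15), and 14 of its 32 members fell over all probes and 24 adjusted over the list alone; adjusted p = 0.478 with an estimated correlation, and fry gave 0.0319. The cyclin gene Ccnb2 fell by 0.59 (SE 0.077), the apoptosis inhibitor and spindle gene Birc5 by 0.59 (SE 0.081), Cdc20 by 0.45 (SE 0.069) and Kif20a by 0.32 (SE 0.042). The interferon list ranked lower (median -0.25, camera adjusted p = 2.77e-13), with 12 of 30 members lower over all probes and 19 adjusted over the list alone; adjusted p = 0.478 with an estimated correlation, and fry gave 0.0275. Irf9, a subunit of the interferon-activated transcription factor, fell by 0.72 (SE 0.054, adjusted p = 2.18e-05), and the interferon-induced genes Ifit1, Ifit2 and Xaf1 fell by 0.73 (SE 0.11), 0.48 (SE 0.078) and 0.40 (SE 0.064). The G1/S list ranked lower by less (median -0.061, camera adjusted p = 0.0253, adjusted p = 0.478 with an estimated correlation), with 4 of 39 members lower over all probes, the cyclin gene Ccne1 (-0.30), the thymidylate synthase gene Tyms (-0.41), the ribonucleotide reductase gene Rrm1 (-0.27) and Mcm4 (-0.27), and 5 adjusted over the list alone. Its call was lost without control-si replicate 4 (0.182) or TIP60-si replicate 4 (0.129), within 5.58e-05 to 0.478 over all alternatives.

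Single adipocyte and lipid genes rose in TIP60-si, while their lists were called only at the preset correlation. The mean of the adipocyte identity array medians was 2.5 over the reference in both TIP60-si (SD 0.033) and control-si (SD 0.17). Over probes far from the reference, the mean slope of the TIP60-si arrays was 1.06 relative to control-si. A wider spread was therefore not separated from the ranks of these lists. Of the adipocyte identity list (median 0.12, camera adjusted p = 0.00128), 5 of 33 members rose over all probes and 6 adjusted over the list alone; adjusted p = 0.524 with an estimated correlation. The fatty acid carrier gene Fabp5 rose by 0.42 (SE 0.056), the seipin gene Bscl2 by 0.40 (SE 0.065), Agpat2 by 0.38 (SE 0.078) and the adipogenin gene Adig by 0.58 (SE 0.14). Of the fatty acid and triglyceride synthesis list (median 0.10, camera adjusted p = 0.0021, adjusted p = 0.478 with an estimated correlation), Agpat2 and the desaturase gene Scd1 (0.60, SE 0.15) rose over all probes and 3 of 23 adjusted over the list alone. Of the lipolysis and lipid droplet list (median 0.15, camera adjusted p = 0.00299, adjusted p = 0.478 with an estimated correlation), Bscl2 and the triglyceride lipase gene Pnpla2 (0.39, SE 0.10) rose over all probes and 7 of 16 adjusted over the list alone. Of the oxidative phosphorylation list (median 0.059, camera adjusted p = 0.00748, adjusted p = 0.488 with an estimated correlation), the complex III gene Uqcrc1 (0.30, SE 0.065) rose over all probes, and 1 of 28 adjusted over the list alone. After scaling to equal spread all 4 calls were lost, and the adipocyte identity median was -0.16, the lipolysis median -0.037 and the oxidative phosphorylation median -0.065. With median centring the synthesis and oxidative phosphorylation calls were lost, and the adipocyte identity and oxidative phosphorylation medians were -0.046 and -0.13. The oxidative phosphorylation call was also lost without control-si replicate 3 (0.109) or 4 (0.0853), within 0.000127 to 0.591 over all alternatives, and 10 of the 35 ways to split the 8 arrays gave 7 or more called lists.

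The remaining 27 lists were not called by camera in TIP60-si, though members of most of them changed. Among them fry called the ATF4 list and the USP7 partners (adjusted p = 0.0275 for both) and the acetyltransferases and deacetylases (0.0319) downward. It called the endothelial markers upward (0.0319). The lists of USP7 partners and of acetyltransferases and deacetylases hold Kat5 itself. Of the ATF4 and unfolded protein response list (median -0.035, camera adjusted p = 0.151), 6 of 28 members fell over all probes, and adjusted over the list alone 9 fell and 1 rose; the folate enzyme gene Aldh1l2 fell by 0.51 (SE 0.054) and the stress pseudokinase gene Trib3 by 0.48 (SE 0.070). Of the p53 target list (-0.088, 0.08), the apoptosome gene Apaf1 fell by 0.44 (SE 0.064) and the kinase gene Plk3 rose by 0.23 (SE 0.059), and adjusted over the list alone 10 fell and 3 rose. Of the list of USP7 partners (-0.031, 0.112), 2 fell, Kat5 and the cell cycle inhibitor gene Cdkn2a (-0.52, SE 0.065), and 4 adjusted over the list alone. Of the NF-kB list (-0.061, 0.139), the subunit gene Nfkb1 fell by 0.62 (SE 0.066) and the chemokine gene Ccl2 rose by 0.40 (SE 0.085); adjusted over the list alone 5 fell and 1 rose. Of the TIP60 complex subunits (median 0.060, mean -0.027, 0.755), Kat5 and Morf4l2 (-0.33, SE 0.053) fell and Vps72 (0.37, SE 0.080) rose, with 3 lower and 2 higher adjusted over the list alone. Of the acetyltransferases and deacetylases (-0.031, 0.151), Kat5 and the deacetylase gene Sirt1 (-0.37, SE 0.055) fell and Hdac6 (0.18) rose, also adjusted over the list alone. Of the lysosome and autophagy list (median 0.018, mean -0.0063, 0.631), the autophagy genes Atg12 (-0.73, SE 0.075) and Wipi1 (-0.20) fell, and adjusted over the list alone 3 fell and 2 rose. Of the preadipocyte markers (0.032, 0.151), Fosl1 (0.66), Thy1 (0.27) and Foxc2 (0.31) rose and Twist1 (-0.34) fell, with 3 higher and 2 lower adjusted over the list alone. In control-si the risers Fosl1 (1.79), Thy1 (0.52) and Foxc2 (0.92) stood above the undifferentiated reference, and Twist1 (-1.86) below it. Of the extracellular matrix list (0.099, 0.137), the protease gene Mmp3 (0.55) and Thbs2 (0.42) rose and Col12a1 (-0.37) and Mmp14 (-0.29) fell, with 6 higher and 4 lower adjusted over the list alone.

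Single members changed in most of the other lists. Ccl2 and the lipase inhibitor gene Angptl4 (0.37) rose among adipokines (median 0.049, camera adjusted p = 0.137), the brown fat regulator gene Prdm16 (0.25) among brown adipocyte markers (0.032, 0.151) and Tek among endothelial markers (0.026, 0.213; 2 adjusted over the list alone). The nucleolar gene Pes1 (-0.27) fell in ribosome biogenesis (0.078, 0.174; 2 higher and 1 lower adjusted over the list alone), the dehydrogenase gene Dld (-0.43) in the citrate cycle (0.052, 0.278) and the repressor gene Nfil3 (-0.32) in the circadian clock (0.035, 0.342; 1 higher and 1 lower adjusted over the list alone). In cholesterol synthesis (median 0.063, mean -0.0084, 0.368) Cyp51 fell and the farnesyl diphosphate synthase gene Fdps (0.28) rose, with 3 lower and 2 higher adjusted over the list alone. The bone regulator gene Runx2 (-0.33) fell among osteoblast markers (0.024, 0.368; 1 higher and 1 lower adjusted over the list alone), the receptor gene Fzd1 (-0.34) and Sfrp2 (-0.27) in Wnt signalling (-0.030, 0.368; 3 adjusted over the list alone) and the kinase gene Pdk4 (-0.28) in fatty acid oxidation (0.034, 0.368). In DNA damage response (-0.039, 0.373) the excision repair gene Ercc1 (0.25) rose and H2ax (-0.23) fell. Fos and Egr1 rose in the heat shock and immediate early list (median -0.021, mean 0.049, 0.534; 3 higher and 1 lower adjusted over the list alone). Apaf1 fell among apoptosis genes (-0.068, 0.621), and Hrk (0.26), Diablo (0.20) and Bcl2l1 (0.39) rose, with 5 lower and 3 higher adjusted over the list alone. Rps18 (-0.20) fell among cytosolic ribosomal proteins (-0.042, 0.616; 2 adjusted over the list alone) and Psma7 (-0.28) in the proteasome (median -0.0024, mean 0.0032, 0.69). For lists with no count beside them, the same number changed adjusted over the list alone. Limma called 0 members of the macrophage (0.026, 0.213), insulin signalling (0.0031, 0.72) and muscle (-0.033, 0.805) lists, with 1, 1 and 0 at an unadjusted p below 0.05. Adjusted over the list alone, of these only the growth factor receptor gene Csf1r of the macrophage list rose (0.36, SE 0.097).

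TIP60-si versus USP7-si tests directly where the knockdowns differ. Apart from Usp7, the genes furthest above USP7-si were Ear10 (1.37, SE 0.14), the mitochondrial thioredoxin gene Txn2 (1.26, SE 0.31, adjusted p = 0.0263), Prl2c3 (1.17, SE 0.15) and Ear-ps9 (1.1), and those furthest below were Papss1 (-1.40, SE 0.088), Cyp51 (-1.19), Lrrc75b (-1.09), Ogn (-0.99) and Cavin3 (-0.97). In all, 3037 probes differed, 1224 higher and 1813 lower in TIP60-si, and 8513 had an unadjusted p below 0.05. Txn2 was uneven in USP7-si, at -1.15 and -1.42 in replicates 1 and 2 and at 0.34 and 0.32 in replicates 3 and 4, and the labels do not say whether these arrays received the same sequence; Txn2 was called under 14 of 25 alternatives. The count was at most 4061, with array quality weights, and it was 41 with median centring and 310 after scaling to equal spread, where Prl2c3 was at -0.83 and Ogn at 1.11, neither called. Leaving out 1 array took it to 1500 (USP7-si replicate 3), 1532 (USP7-si replicate 1), 1614 (TIP60-si replicate 3) or 1895 (USP7-si replicate 4).

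Between the knockdowns 12 lists were called at the preset correlation, and 0 with an estimated correlation. The adipocyte identity list ranked higher in TIP60-si than in USP7-si (median 0.24, camera adjusted p = 6.56e-06, adjusted p = 0.5 with an estimated correlation), with 8 of 33 members higher over all probes and 11 adjusted over the list alone, among them Fabp5 (0.46), Agpat2 (0.58), Adig (0.78) and the lipid droplet gene Cidec (0.54). Lipolysis and lipid droplet genes ranked higher too (median 0.25, camera adjusted p = 0.000592, adjusted p = 0.5 with an estimated correlation), with 8 of 16 members higher, also adjusted over the list alone, among them the hormone-sensitive lipase gene Lipe (0.63). So did fatty acid and triglyceride synthesis genes (0.12, 0.000611, adjusted p = 0.5 with an estimated correlation), with 4 of 23 higher, 7 adjusted over the list alone, among them Scd1 (0.79). Oxidative phosphorylation genes ranked higher by less (0.089, 2e-04, adjusted p = 0.5 with an estimated correlation), with 3 of 28 higher, also adjusted over the list alone. The G1/S list ranked higher (0.15, camera adjusted p = 0.000325, adjusted p = 0.5 with an estimated correlation), with 10 of 39 members higher, such as the clamp loader gene Rfc3 (0.38) and Tk1 (0.34), and 2 lower; adjusted over the list alone these were 13 and 4. Ribosome biogenesis genes (0.095, 0.00304, adjusted p = 0.192 with an estimated correlation) had 6 of 21 members higher, among them Myc (0.46); adjusted over the list alone 8 were higher and 1 lower. Lower in TIP60-si ranked the interferon list (-0.13, 0.00327, adjusted p = 0.648 with an estimated correlation; 5 of 30 lower, 8 adjusted over the list alone) and the p53 target list (-0.090, 0.00979, adjusted p = 0.5 with an estimated correlation), where 8 of 27 members were lower, among them Apaf1 (-0.55), Trp53inp1 (-0.60), Sesn1 (-0.27) and Btg2 (-0.44), and 12 adjusted over the list alone. The citrate cycle (0.058, 0.0158), proteasome (0.050, 0.025) and adipokine (0.086, 0.0476) lists ranked higher and the acetyltransferase and deacetylase list, which holds Kat5, lower (-0.075, 0.0378), with adjusted p = 0.5, 0.286, 0.547 and 0.5 with an estimated correlation. Of these 4 lists, 2, 1, 2 and 0 members were higher and 1, 1, 1 and 4 lower; adjusted over the list alone 4, 1, 3 and 1 were higher and 1, 1, 1 and 8 lower. The mitosis list had a median of -0.058 (camera adjusted p = 0.998), with 1 member higher, Racgap1 (0.32, SE 0.089), and 1 lower, Birc5 (-0.29, SE 0.081), over all probes and adjusted over the list alone. Of the alternatives, only the estimated correlation and fry (7 lists called) were run on the lists between the knockdowns. No array was left out for them, and USP7-si replicate 4 had the lowest adipocyte identity median (1.70, other USP7-si arrays 2.255 to 2.49). Over probes far from the reference, the mean slope relative to control-si was 1.06 in TIP60-si and 0.942 in USP7-si. A difference in spread was therefore not separated from the higher adipocyte and lipid lists.

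The other 21 lists were not called by camera between the knockdowns. Camera adjusted p was 0.191 for fatty acid oxidation (median 0.021) and Wnt signalling (-0.042), 0.234 for NF-kB genes (-0.065), 0.276 for osteoblast markers (0.0093) and preadipocyte markers (0.056), 0.282 for DNA damage response (0.038) and 0.285 for the extracellular matrix (0.018) and cholesterol synthesis (-0.038). It was 0.37 for the heat shock and immediate early list (-0.030), 0.383 for brown adipocyte markers (0.021), 0.409 for insulin signalling (0.043), 0.521 for apoptosis (-0.059), 0.564 for cytosolic ribosomal proteins (0.057) and 0.6 for macrophage markers (0.00065) and the circadian clock (0.018). It was 0.719 for TIP60 complex subunits (median 0.0053, mean -0.018), 0.776 for USP7 partners (0.045), 0.875 for the ATF4 list (median 0.0014, mean -0.037) and the lysosome and autophagy list (median 0.0016, mean -0.020), 0.958 for muscle markers (-0.0033) and 0.962 for endothelial markers (-0.026). Members still differed. Fosl1 of the preadipocyte list, at 1.79 over the reference in control-si, was higher in TIP60-si by 0.86 (SE 0.12). The matrix proteoglycan gene Bgn was higher by 0.79 (SE 0.15). Nfkb1 (-0.74, SE 0.066), Atg12 (-0.75, SE 0.075) and Runx2 (-0.52, SE 0.078) were lower. Fos (-0.29, SE 0.082) and Egr1 (-0.39, SE 0.11), higher in both knockdowns than in control-si, were lower in TIP60-si than in USP7-si. Limma called 0 members of the insulin signalling, macrophage and muscle lists over all probes or adjusted over the list alone, with 4, 0 and 1 at an unadjusted p below 0.05.

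The knockdowns shared 21 called probes, all in the same direction: 5 higher, 16 lower and 0 opposite, among 2580 probes in USP7-si and 7090 in TIP60-si with an unadjusted limma p below 0.05. The 5 higher were Fos (0.88 in USP7-si, 0.59 in TIP60-si), Egr1 (0.89, 0.50), Ablim1 (0.49, 0.53), Olfr598 (0.43, 0.35) and Tek (0.35, 0.27). The other probe of Tek was at -0.0035 in USP7-si and 0.035 in TIP60-si. Among the lower were Bag6 (-0.52, -0.48), H2ac23 (-0.54, -0.45), Lars2 (-0.42, -0.51), Set (-0.39, -0.41) and H2ac13 (-0.58, -0.37). Outside the rule, and chosen after their values were seen, the histone H2A genes H2ac1, H2ac7, H2ac10 and H2ac15, the nuclear import gene Kpna2 and the condensin gene Ncapd2 (-0.26, -0.26) were also lower in both. Independent lists of these sizes would share 0.163 higher and 0.556 lower probes, a number that leaves out the effect of the shared controls. With the control arrays split between the knockdowns, 5 to 8 probes were shared. Each knockdown then had fewer control arrays, and only 8 to 19 probes were called in USP7-si and 320 to 1409 in TIP60-si. Without 1 array the count was 9 (control-si replicate 4), 11 (control-si replicate 2 or USP7-si replicate 1) or 13 (TIP60-si replicate 2); it was 0 with median centring and 2 after scaling to equal spread.

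**Figure D3:**
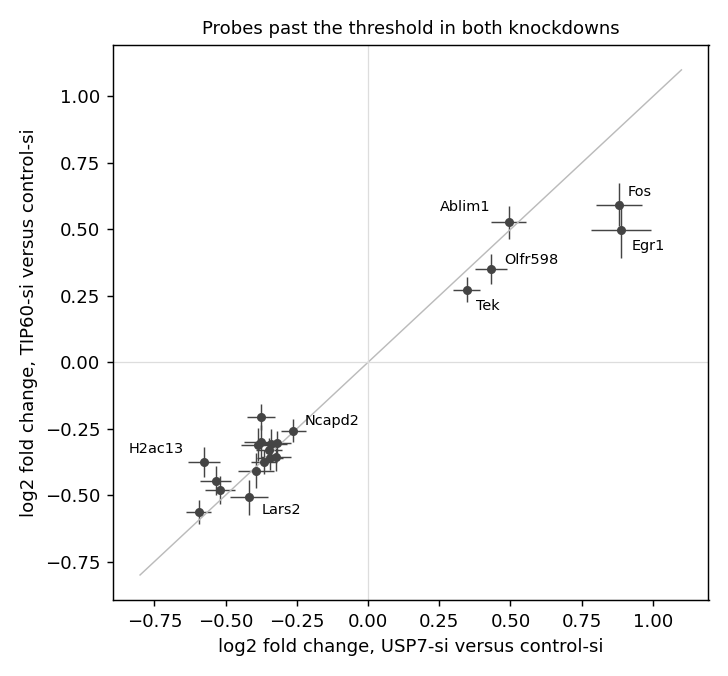
Log2 fold change against control-si in USP7-si (horizontal) and TIP60-si (vertical) of the 21 probes called in both, with SE bars; the diagonal marks equal change. The 5 higher and 16 lower probes lie near the diagonal, with Fos and Egr1 below it.

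With the control arrays split, the correlation of the knockdowns' fold changes across all probes ranged from -0.221 to 0.00846. With shared controls the covariance was 0.00129, against a mean of 0.00221 in simulated unchanged groups with the same controls. Over probes far from the reference, the mean slope relative to control-si was 0.942 in USP7-si and 1.06 in TIP60-si. A difference in spread was therefore not separated from these values, and no array was left out for them. Of the 1556 probes called in TIP60-si, 1111 also differed between the knockdowns with the same sign. Of the 35 called in USP7-si, 15 differed between the knockdowns, counted whatever the sign. Both comparisons behind each count use the same knockdown arrays, which alone favours overlap. The counts therefore do not measure how particular either response is.

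The last comparison set each response against the difference between control-si adipocytes and the undifferentiated reference. Across probes, the correlation was -0.32 for USP7-si (covariance -0.0122, range -0.42 to -0.23 over 4 splits of the controls) and 0.19 for TIP60-si (covariance 0.00981, range 0.10 to 0.28). With the same control arrays on both sides the values were -0.46 and 0.16. They depended on single arrays: the USP7-si value was -0.16 without USP7-si replicate 4 (-0.162) or control-si replicate 2 (-0.159), and the TIP60-si value 0.10 without control-si replicate 1, 0.12 without control-si replicate 3 and 0.29 without control-si replicate 2. The USP7-si value was -0.12 with no background correction (-0.116) or with the authors' values (-0.118), and -0.15 with median centring. After scaling all arrays to an equal spread both signs turned, to 0.61 and -0.22.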

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

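The tests of a uniform shrinkage of the log ratios and of the loess normalization, and the scaling of all arrays to an equal spread, were chosen after the results were seen; the other tests here were written before.

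In 7 of 144 groups of 4 values, 1 array lay far from the other 3 for the size of the group's range. Chance marks about 1 in 20 groups, which is 7.2 here, so their number is no more than chance gives. On the log2 scale over the reference, Fos was at -1.05 in control-si replicate 3 (others -0.835 to -0.809), Hoxa7 at -0.68 in control-si replicate 1 (others -0.883 to -0.849) and Kat5 at -0.389 in control-si replicate 2 (others -0.14 to -0.0902). Mcm6 was at 0.3 in TIP60-si replicate 4 (others 0.459 to 0.482) and Lrrc75b at -1.53 in TIP60-si replicate 3 (others -1.39 to -1.37). Pdgfa was at -1.01 in USP7-si replicate 4 (others -1.08 to -1.07), and the interferon list median was 0.294 in USP7-si replicate 3 (others 0.114 to 0.13).

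The 8 arrays of 2 groups can be split into 4 and 4 in 35 ways. A first rank of the real split, which chance gives in 1 of 35 cases, is the strongest outcome possible, so it makes chance unlikely without excluding it. Where groups differ, the other splits mix them, which widens the spread and lowers their counts. Splits that keep most arrays of a group together also hold part of a real difference, which can raise their counts. For the USP7-si lists the highest other split set control-si replicate 2 with USP7-si replicates 1, 2 and 3. For the TIP60-si lists it set TIP60-si replicate 1 with control-si replicates 1, 3 and 4. The other splits are therefore not counts without an effect. For USP7-si versus control-si, 1 split, the real one, gave 35 or more probes, and the highest other gave 19. Among its gene lists the real split also ranked first, but narrowly, with 13 called lists against 11 and a median of 6 over the other splits. For TIP60-si versus control-si, 1 split, the real one, gave 1556 or more probes and the highest other gave 0, which makes chance unlikely. For its gene lists, 10 of the 35 splits gave 7 or more and the highest other gave 11, with a median of 4, so chance cannot be excluded for that number. For TIP60-si versus USP7-si, 1 split, the real one, gave 3037 or more probes and the highest other gave 1, which makes chance unlikely.

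Mitosis genes stood lower in both knockdowns, by a median of -0.329 in USP7-si and -0.309 in TIP60-si. A uniform shrinkage of the log ratios as the whole cause is argued against by the mean slope of the arrays over 1283 probes far from the reference, relative to control-si: it was 0.942 (SD 0.0589) in USP7-si, where the fall needs 0.732, and 1.06 (SD 0.0154) in TIP60-si, where it needs 0.748. The slope in USP7-si alone would give a median of -0.0714, so a part of the size there stays open, and after scaling to equal spread the medians were -0.0571 and -0.407. The adipocyte identity list in USP7-si, at -0.0915 where shrinkage needs -0.679, decided nothing with all 4 arrays (SD 0.354); without USP7-si replicate 4 it was at 0.00868 and the mitosis list at -0.272. Control arrays that stand apart are argued against by the median nearest to 0 without 1 control array, -0.262. With median centring or the authors' values, the median nearest to 0 was -0.25. The authors' values were loess normalized too, so they cannot test the intensity-dependent normalization. Median centring, with medians at -0.25 or further below 0, argues against it. No biological explanation was tested.

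Silencing Kat5 moved more probes past the threshold than silencing Usp7. The ratio of the counts was at least 25.3 without any 1 TIP60-si array, which argues against a single array as the whole cause. With median centring in place of loess the ratio was 8.67, which argues against loess as the whole cause. That ratio rests on few probes, since both counts fell far below the 1556 and 35 found with loess, so the size of the excess depended on loess. Off-target effects of the small interfering RNAs stay open, since their sequences are not given. Protein levels of the targets were not analysed here, and no biological explanation was tested.

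The USP7-si response ran against the difference between adipocytes and undifferentiated cells, with a mean correlation of -0.321. Leaving out 1 USP7-si array left it at -0.162 at the nearest to 0, so no single array of that group makes all of it. Scaling the arrays to an equal spread turned it to 0.609. That goes with an unequal spread between arrays as the cause but cannot decide it. The scaling multiplies every log ratio of an array by 1 factor, set by its median absolute ratio. That ratio was 0.0554 in USP7-si replicate 4 (other arrays 0.109 to 0.148), while the slope of its far probes was 0.854. So the scaling stretched these probes by more than their slope asks, which alone moves the correlation upward. An unequal spread stays open. No conclusion on a loss of adipocyte identity is drawn from this correlation.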

How the results depend on the processing

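Scaling to an equal spread, for all results, and median centring, for the gene lists, were chosen after seeing the data; the other alternatives were planned. Of 1965 values of single genes and lists under the alternatives, 1624 kept the direction of their test and their side of the threshold, 329 kept that direction but missed the threshold, and in 12 it turned. These include Aquantile scaling, which leaves log ratios as they are. They also include fits without an array of the group outside the comparison. Such fits keep every array of the groups compared, so this tally and the counts of alternatives per gene overstate stability. Some results still moved there, since all groups share the same estimate of the spread. The USP7-si count and the cytosolic ribosomal call in USP7-si changed without single TIP60-si arrays. The direction of a list's test can differ from the sign of its median: 3 more list medians changed sign, lipolysis in TIP60-si (-0.0373) and the proteasome in USP7-si (0.00245) after scaling to an equal spread, and adipocyte identity in TIP60-si (-0.0462) with median centring. Below, counts of probes are in the order USP7-si versus control-si, TIP60-si versus control-si, TIP60-si versus USP7-si. Except where fewer arrays or a stricter test make it plain, the cause was not tested.

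Plain background subtraction gave 12, 640 and 1084 probes, and median centring 3, 26 and 41, with 0 probes changed in both, 8 and 12 called lists in USP7-si and TIP60-si, and oxidative phosphorylation in TIP60-si at -0.125. Scaling to an equal spread gave 4, 97 and 310 probes and 2 changed in both, and left Usp7 at -2.15 without a call (adjusted p = 0.112). There Ccn1 was at -0.141 and Lars2 at 0.0438 in USP7-si, and Prl2c3 at -0.826 and Ogn at 1.11 between the knockdowns. Of the lists in USP7-si, cholesterol synthesis was at -0.102, adipocyte identity at 0.489, the citrate cycle at 0.179 and oxidative phosphorylation at 0.225; in TIP60-si, adipocyte identity was at -0.157 and oxidative phosphorylation at -0.0653.

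Without the dye term the counts were 18, 602 and 1373, with unmoderated statistics 18, 559 and 1398, and with a log2 fold minimum of 0.5 they were 11, 126 and 216. For USP7-si versus control-si, eBayes with trend and robust settings gave 16 and array quality weights 77. In USP7-si and TIP60-si, an estimated correlation called 3 and 0 lists, and fry 7 and 6. With split controls, 5, 8, 6 and 5 probes changed in both, where 8 to 19 were called in USP7-si. The correlation with the adipocyte difference in USP7-si was -0.116 with no background correction, -0.152 with median centring, -0.118 with the authors' values, -0.462 with the same controls on both sides and 0.609 after scaling, where that of TIP60-si was -0.217.

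Leaving out each array in turn gave 14 to 49, 736 to 1797 and 1500 to 3353 probes, 9 to 14 and 5 to 9 called lists, and 9 to 23 probes changed in both. The USP7-si count was 14 without control-si replicate 4 or USP7-si replicate 1, 16 without control-si replicate 2, 18 without USP7-si replicate 4 and 21 without USP7-si replicate 3. The TIP60-si count was 859, 736 and 743 without control-si replicates 1, 2 and 4 and 884 without TIP60-si replicate 3. The count between the knockdowns was 1614 without TIP60-si replicate 3 and 1532, 1500 and 1895 without USP7-si replicates 1, 3 and 4. Probes changed in both were 11 and 9 without control-si replicates 2 and 4, 13 without TIP60-si replicate 2 and 11 without USP7-si replicate 1. The correlation ranged from -0.377 to -0.159 in USP7-si (-0.159 without control-si replicate 2, -0.162 without USP7-si replicate 4) and from 0.103 to 0.288 in TIP60-si (0.103, 0.288 and 0.115 without control-si replicates 1, 2 and 3). Usp7 ranged from -1.72 to -1.52 and Kat5 from -1.08 to -0.966. The adipocyte identity median in USP7-si was 0.00868 without USP7-si replicate 4.

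With replicate as a block, the counts were 37, 1715 and 3353, with 13 and 7 called lists, 20 probes changed in both, correlations of -0.257 and 0.185, Usp7 at -1.64 and Kat5 at -0.999. Print-tip loess equals loess here, since the files give 1 print block, and Aquantile scaling leaves log ratios as they are. A filter on bad spots and a block for slide or scan were not run, since the files give neither. On the array with the lowest share, 85.2% of gene probes stood above background, which limits what dim probes show.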

Other observations

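The values here were looked up after the results were seen, and no test was run on them beyond the limma calls stated.

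Of 10 probes of clustered H2A genes, limma called 6 lower in USP7-si (median -0.346, range -0.575 to 0.0495) and 8 lower in TIP60-si (median -0.298, range -0.445 to -0.0749). Of 11 H2B probes it called 0 and 1 lower (medians 0.0681 and -0.0646), of 4 H3 probes 0 and 1 (-0.112 and -0.187), and of 6 H4 probes 0 and 0 (-0.0654 and -0.0228). The H2A medians stayed below 0 with no background correction, median centring, the authors' values and scaling to equal spread (-0.112 in USP7-si, -0.373 in TIP60-si), and the H4 median in USP7-si turned to 0.2 after scaling. The H2A genes are close in sequence, and whether each probe reads 1 gene was not analysed here.

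Both probes of Txn2 were uneven within USP7-si, and the labels do not say whether its 4 arrays received the same small interfering RNA. Probe MMAB004861 was at -0.763 and -1.02 in replicates 1 and 2 and at 0.488 and 0.465 in replicates 3 and 4, and probe MMAB035439 at -1.15 and -1.42, and 0.337 and 0.318. Acbd6, which carries an acyl-CoA binding domain, was at -1.14 and -1.2 in replicates 1 and 2 and at -0.214 and -0.178 in replicates 3 and 4.

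Probes without a symbol were among the largest changes in USP7-si. Probe MMAB008626 rose by 1.07 (SE 0.0761, adjusted p = 2.91e-05 in limma), and MMAB000782 by 0.651. Probe MMAB030872 was lower in both knockdowns, at -0.594 in USP7-si and -0.564 in TIP60-si.

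USP7-si replicate 4 had compressed log ratios. Its slope against the mean of the 12 arrays, over the 1283 probes with a mean log2 ratio beyond 1 in either direction, was 0.854, where the other 11 arrays lay between 0.953 and 1.08.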
